A study of Mus musculus with 2 samples.

How the data were processed

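ATAC-seq, which marks accessible chromatin by the insertion of a transposase, was measured in activated regulatory T cells of male mice aged 4 months that carry Foxp3CreERT2 and Rosa26YFP alleles. The series holds 2 libraries, which the labels number as technical replicates 1 and 2 of biological replicate 1. Both belong to 1 group, and the labels name no control or comparison group. The values analysed come from 3 peak lists of the whole series on the mouse build mm10: a pseudoreplicated list, a list ranked by irreproducible discovery rate (IDR) and a list past an IDR threshold. Per the README that accompanies each library, all 3 derive from 1 alignment, so no value belongs to a single library. A leave-one-out analysis of replicates was therefore not possible, and no SD between animals can be given. The aligner, the peak caller, the read filters and their versions are not given in the sources used here, and neither is any adjustment of read positions for the transposase. Genome-wide signal tracks and alignments were not used here. The sequencing depth behind the lists is unknown.

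The deposited signal value of each peak is the enrichment written by the peak caller, and what it is relative to is not given in the sources used here. The deposited −log10 p and −log10 q columns hold the caller's own p-value and q-value per peak. In the ranked list, the deposited −log10 columns also hold the local and global IDR and the ranking value of each peak in the 2 inputs that were compared. The deposited score runs to 1000. In the ranked and thresholded lists it follows from the global IDR, and its lowest value in the thresholded list corresponds to an IDR of 0.05. All of these values are the authors' own per-peak values, and they were used here to describe, rank or filter peaks within a list.

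Peaks that overlapped by 1 bp or more were merged into regions, and each region took the signal and summit of its strongest peak. The stricter list held peaks with a global IDR of 0.01 or below. Genes and transcription start sites (TSSs) came from the GENCODE M21 annotation of GRCm38.p6, the assembly of mm10, for the 21938 protein-coding genes of chromosomes 1 to 19, X and Y. Regions were classed by the location of the strongest summit, in the order promoter (within 1000 bp of a protein-coding TSS), 5' UTR, coding exon, 3' UTR, intron and intergenic. A gene had a promoter region when a region lay within 1000 bp of any of its TSSs. Each region was assigned to the gene with the nearest TSS within 100 kb of its summit, and a region was distal when it lay over 1000 bp from every protein-coding TSS. For motifs, a summit was distal when the summit itself lay over 1000 bp from every protein-coding TSS. A distal summit can thus lie in a region that reaches a promoter.

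The 26 gene lists, the 32 consensus motifs, the tests and the alternatives were fixed before the data were examined. Promoter regions of a list were compared with those of all other protein-coding genes by Fisher's exact test, two-sided. Regions per gene were compared by a two-sided permutation test on the mean of log2(regions + 1), with 10000 random lists drawn from genes in the same of 10 classes of territory size, the bases nearest to a gene's TSS. The smallest p these permutations can give is 1e-04. Motif matches on either strand within 100 bp of a summit were compared with a window of the same width centred 1000 bp away by an exact McNemar test, two-sided. Matches at distal and promoter summits were compared by Fisher's exact test. Each family of tests was adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. Genes and summits are not replicates, so these p-values ask whether a list or motif stands apart within these pooled libraries. Peaks of 1 region lie close together and share sequence, which makes the motif p-values too small. Shares carry Wilson 95% intervals, which cover counting error only.

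Genes were named by a rule also fixed before the data were examined: 14 genes in every case, up to 4 members of each list with the most regions and up to 2 with none, the 20 genes with the most regions, the 10 with the strongest promoter region, and the genes nearest to the 10 strongest distal regions. Fewer are given where length required it. Alternatives covered the pseudoreplicated and stricter lists, unmerged peaks, an overlap of 50%, promoter windows of 500 and 2500 bp, 1 TSS per gene, assignment within 50 and 20 kb, no matching on territory, motif windows of 50 bp and shuffled windows as background. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and sequence copies were sought with blastn 2.17.0. On simulated data with 5 altered lists, the promoter test called 91 of 100 altered and 5 of 360 unaltered lists, and the test of regions per gene called 100 of 100 and 4 of 360. Unaltered lists that share a gene with an altered list were left out of these counts. Simulated genes were independent, with equal promoter odds and counts proportional to territory, and fewer random lists were drawn. The rates need not hold for the real genes and overlapping lists. The motif test found 15 of 15 planted motifs and called 0 of 145 others. Its simulated summit and flank windows had the same base composition, unlike the real ones. It therefore does not measure false calls that arise from a difference in GC content.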

Results

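Accessible chromatin was profiled in activated regulatory T cells, the Foxp3-expressing CD4 T cells that restrain other immune cells. The 2 libraries are technical replicates of 1 biological replicate, and the deposited peak lists describe them together. No other cell type or state was measured, so the comparisons below set genes, gene groups, motifs and chromosomes against each other within these cells. There are no replicates behind any value, and the read depth is unknown.

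The IDR thresholded list held 48668 peaks on 26090 distinct intervals, each listed once per summit. The 26090 merged regions were these intervals and covered 17.8 Mb, or 0.674% of the genome. The median region was 637 bp wide with a median signal value of 13.6 (quartiles 9.89 and 17.97). More than 1 summit was present in 52.9% of regions, and up to 9 summits were found in a single region. The pseudoreplicated list held 77257 peaks in 50037 regions, which covered 26.3 Mb and were narrower and weaker, with a median width of 441 bp and a median signal of 8.65. Of the pseudoreplicated regions, 26039 (52.0%, 95% interval 51.6 to 52.5) were also in the thresholded list. Those found in both had a median signal of 13.6, against 5.74 for the 23998 pseudoreplicated regions absent from the thresholded list. Across the 78114 ranked peaks, the −log10 p values of the 2 inputs had a Pearson correlation of 0.773 on the log2 scale and a Spearman correlation of 0.735. They lay within 2-fold of each other at 80.5% of peaks. These are correlations across peaks, which are not independent replicates, and the origin of the 2 inputs is not given in the sources used here. Because the lists derive from 1 alignment, the correlations cannot be read as agreement between the 2 libraries.

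Promoters held 11022 of the thresholded regions, or 42.2% (95% interval 41.6 to 42.8), although promoter windows make up 3.70% of the genome, an 11.4-fold excess. Introns held 27.8% of regions and intergenic sequence 28.0%, which were 0.818 and 0.466 times their shares of the genome. Coding exons held 0.832% and 3' UTRs 1.02%. Promoter regions were wider and stronger than the rest, with a median width of 832 bp and a median signal of 15.4, against 512 bp and 12.1 in introns and 548 bp and 13.1 in intergenic sequence. More than 1 summit was present in 73.4% of promoter regions, in 35.4% of intronic and in 40.2% of intergenic regions. The promoter share was 30.1% in the pseudoreplicated list and 48.8% in the stricter list.

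**Figure D1:**
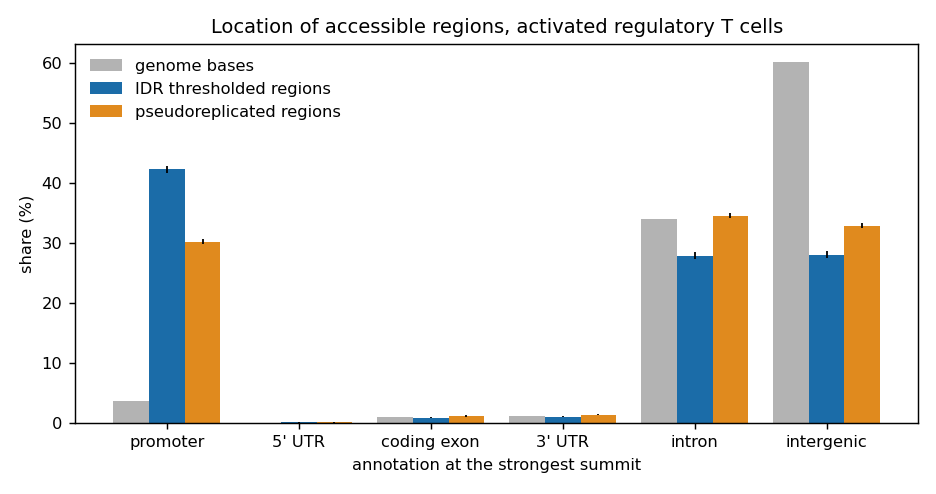
Share of regions (y axis, %) by annotation at the strongest summit (x axis), beside the share of genome bases in each class. Bars with Wilson 95% intervals show the thresholded and pseudoreplicated regions of the pooled libraries: promoters hold 42.2% and 30.1% of regions but 3.70% of bases.

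Promoter regions were more common among pan-T cell, regulatory T cell core, signalling, interferon response, cell cycle and housekeeping genes than among other genes, and less common among liver, NK cell, stem cell and neuronal genes. Of all protein-coding genes, 10774 of 21938 (49.1%) had a promoter region. All 24 cell cycle genes (such as Ccnd2, Cdk6 and Aurka), all 18 housekeeping genes (such as Actb and B2m) and all 16 genes of interleukin-2 and STAT signalling (such as Il2ra, Jak1 and Socs1) had one. So did 24 of 25 genes of T cell receptor and NF-kB signalling, 14 of 15 AP-1 and related bZIP factors, 12 of 14 interferon response genes, 21 of 25 pan-T cell genes and 17 of 20 regulatory T cell core genes. These 8 lists were called higher than other genes by Fisher's exact test, with adjusted p from 9.95e-07 for the cell cycle list to 0.0153 for the interferon response, and 0.00467 for the regulatory T cell core. In the other direction, none of the 10 liver genes, 9 NK cell genes or 9 stem and progenitor genes had a promoter region, and 1 of 10 neuron and glia genes did (Syn1). Those 4 lists were called lower, with adjusted p of 0.00642, 0.0103, 0.0103 and 0.0469 by Fisher's exact test.

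For the remaining 14 lists the promoter share was not called different. It was 13 of 20 for effector regulatory T cell genes, 11 of 15 for naive or resting T cell genes, 14 of 24 for migration receptors and 7 of 9 for co-inhibitory receptors. Among lists of other T cell states it was 6 of 10 for Th1, 2 of 8 for Th2, 2 of 9 for Th17, 6 of 8 for follicular helper and 6 of 13 for CD8 and cytotoxic genes. It was 5 of 15 for B cell, 4 of 17 for myeloid, 3 of 10 for erythroid and megakaryocyte, 1 of 9 for muscle and 1 of 9 for epithelial genes. In the stricter list the regulatory T cell core had an adjusted p of 0.0662 by Fisher's exact test and was no longer called (range over its 5 alternatives 0.000181 to 0.0662). The call for neuron and glia genes was lost in the pseudoreplicated list (adjusted p = 0.173 by Fisher's exact test), with promoter windows of 2500 bp (0.0991) and with 1 TSS per gene (0.0506), and that for stem and progenitor genes in the pseudoreplicated list (0.134), with ranges of 0.00868 to 0.173 and 0.00430 to 0.134. Other settings added calls by Fisher's exact test: in the pseudoreplicated list Th1 (adjusted p = 0.00817), naive or resting T cell (0.00817), co-inhibitory (0.0125) and migration genes (0.0396) were higher and muscle genes lower (0.0246), and in the stricter list B cell (0.0333), myeloid (0.0458), erythroid (0.0458) and epithelial genes (0.0119) were lower. Naive or resting T cell and co-inhibitory genes were also higher, and muscle and epithelial genes lower, with windows of 2500 bp, and myeloid genes were lower with windows of 500 bp.

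Genes of naive or resting T cells had a median of 7 regions, 2.02 above matched random lists on the log2(regions + 1) scale (SD of random lists 0.26). T cell receptor and NF-kB signalling genes had a median of 6 (difference 1.92, SD 0.19), pan-T cell genes a median of 5 (1.70, SD 0.19), regulatory T cell core genes a median of 4 (1.56, SD 0.19) and effector regulatory T cell genes a median of 4 (1.12, SD 0.21). Interleukin-2 and STAT signalling (1.44), AP-1 and related factors (1.35), co-inhibitory receptors (1.27) and migration receptors (1.14) were raised to a similar extent. Housekeeping genes (0.83), cell cycle genes (0.77), follicular helper genes (1.08, adjusted p 0.00672 by permutation) and interferon response genes (0.46, adjusted p 0.0206) were raised as well. In all, 15 of the 26 lists were called higher by the permutation test. Of these, 11 had the smallest p the permutations can give (1e-04, adjusted p 0.000236), and the weakest calls were Th1 (difference 0.68, adjusted p 0.0326 by permutation) and CD8 and cytotoxic genes (0.48, adjusted p 0.0458). Liver genes, with 1 region among 10 genes, were called lower (−0.69, adjusted p 0.0154). The B cell (0.00), epithelium (0.00), Th17 (−0.01), NK cell (−0.05), myeloid (−0.15), erythroid (−0.25), muscle (−0.34), stem and progenitor (−0.39), neuron (−0.49) and Th2 (0.38) lists were not called. The Th1 call was lost in the stricter list (adjusted p = 0.164 by permutation) and with unmerged peaks (0.212), against a lowest value of 0.00120 over its 6 alternatives. The CD8 call was lost under those settings and without matching (adjusted p by permutation from 0.0979 to 0.301, lowest elsewhere 0.00399), and the interferon call was lost without matching (0.252, lowest 0.000473). Calls were added for Th2 genes, higher in the pseudoreplicated list (difference 0.97, adjusted p 0.00399 by permutation), for stem and progenitor genes, lower with assignment within 20 kb (−0.64, 0.0254), and for neuron genes, lower in the stricter list (−0.55, 0.0425).

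Distal regions alone put naive or resting T cell genes 2.11 above matched lists, T cell receptor and NF-kB genes 1.78, pan-T cell genes 1.69, regulatory T cell core genes 1.48, co-inhibitory receptors 1.32, interleukin-2 and STAT genes 1.16, effector regulatory T cell genes 1.16 and follicular helper genes 1.15. Cell cycle (0.31, adjusted p 0.0279 by permutation) and housekeeping genes (0.45, adjusted p 0.00402), whose promoters were all accessible, had smaller differences. Migration receptors, with 71 distal regions among 24 genes, and Th1 (0.80), Th2 (0.57), CD8 and cytotoxic (0.51) and AP-1 genes (1.01) made up the 15 lists called higher, and none was called lower. Interferon response genes were not called (0.19, adjusted p 0.213 by permutation), nor were NK cell (0.35), epithelium (0.33), Th17 (0.29), B cell (0.14), myeloid (0.12), muscle (−0.06), stem and progenitor (−0.07), erythroid (−0.16), neuron (−0.22) and liver genes (−0.31). The Th2 call was lost in the stricter list (adjusted p = 0.0928 by permutation) and without matching (0.101), the cell cycle call in the pseudoreplicated list (0.124) and without matching (0.244), and the housekeeping call without matching (0.194). In the pseudoreplicated list Th17 (0.802, adjusted p 0.0324 by permutation), interferon response (0.603, 0.00353) and NK cell genes (0.746, 0.0117) were called higher, and interferon response genes also in the stricter list (0.0419).

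**Figure D2:**
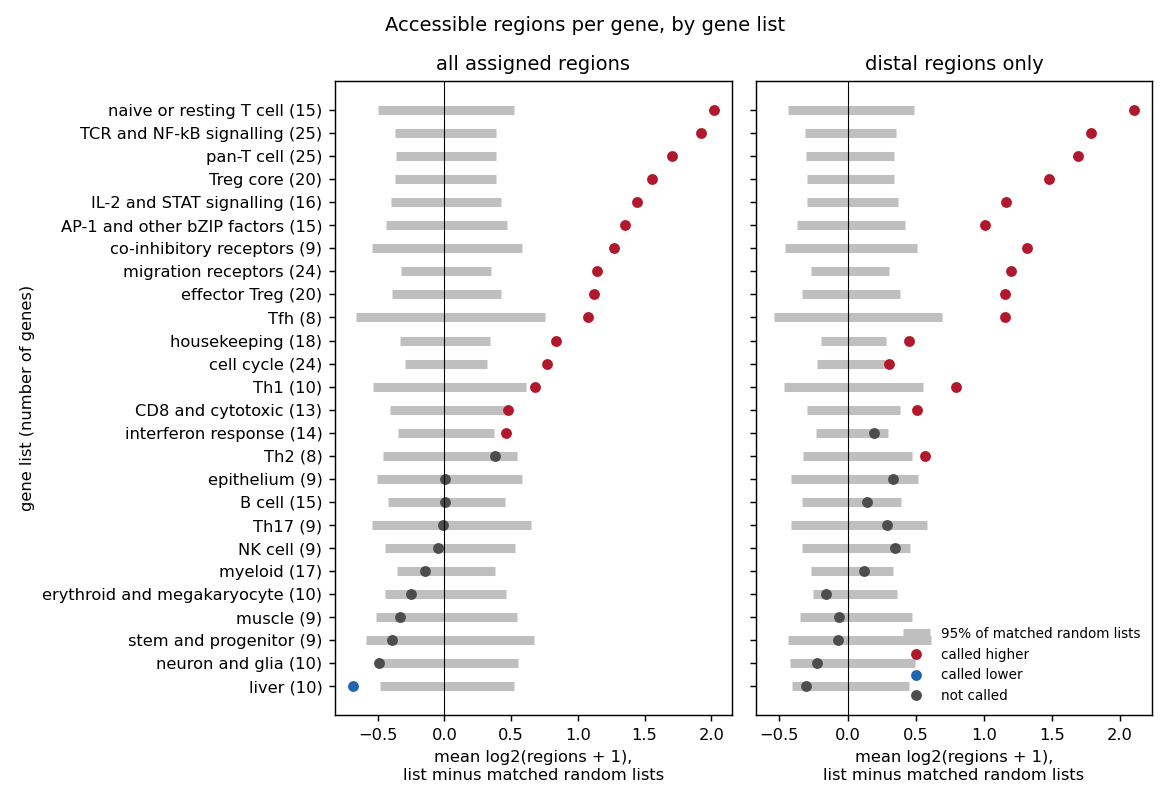
Mean log2(regions + 1) of each gene list minus that of matched random lists (x axis), for all assigned regions (left) and distal regions (right), with list sizes in parentheses on the y axis. Grey bars span 95% of 10000 random lists: the naive or resting T cell list lies at 2.02 and 2.11, and the liver list at −0.69 is the only list called lower.

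Among the regulatory T cell core genes, all 20 had at least 1 region. Counts of single genes, here and below, are not adjusted for territory size. Ctla4, the inhibitory receptor that competes with Cd28 for its ligands, had 14 regions between positions 60823017 and 60941552 of chromosome 1, of which 12 were distal. Entpd1, which encodes the ectonucleotidase CD39, had 11, Tigit had 9 and Ikzf2, which encodes Helios, had 8. The strongest Ikzf2 region lay at chromosome 1, 69752694 to 69753401, in intergenic sequence 65665 bp upstream of the gene's 5' end, with a signal of 17.8 against 6.57 at the promoter. Il2ra, the high-affinity subunit of the interleukin-2 receptor, had 7 regions on chromosome 2, with 1 at its promoter (11642299 to 11643002, signal 10.03), 1 upstream and 5 in introns, the strongest of these at 11653348 to 11653735 (signal 9.82). Tnfrsf18, which encodes GITR, had 4 regions, all distal, and none within 1000 bp of its TSSs.

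Effector regulatory T cell genes were led by Cd44 with 12 regions, Tnfrsf1b with 10, and Irf4 and Tnfrsf9 with 9 each. Il10, which encodes a suppressive cytokine, had 4 distal regions on chromosome 1 and no promoter region, and its strongest region (131010410 to 131010994, signal 19.8) lay 9150 bp upstream of the gene. Ccr8, a chemokine receptor of effector regulatory T cells, had 2 regions, both at its promoter. Klrg1, a marker of terminal differentiation, had 3 distal regions. Ebi3 and Fgl2 had none in the thresholded list, and 1 and 7 in the pseudoreplicated list, where both had a promoter region. Pparg, named after its values were seen, had none in either list.

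The 15 genes of the naive or resting T cell list held 137 regions. Bach2, a repressor that limits effector differentiation, ranked highest of all protein-coding genes by count with 30 regions, of which 26 were distal. The Bach2 territory was 450 kb, against 183 kb for Prkch, which had 26 regions. Foxp1 had 24 regions, S1pr1 had 15 and Lef1 had 12. Tcf7, which encodes TCF-1, had 8 regions, all over 1000 bp from its TSSs, the strongest at chromosome 11, 52299596 to 52300170 (signal 17.2), in intergenic sequence 16806 bp upstream.

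Signature cytokine genes of other helper lineages differed widely. Ifng, the Th1 cytokine, had 10 regions on chromosome 10, 1 at its promoter (118440554 to 118441188, signal 10.7) and the strongest 21946 bp upstream (118418770 to 118419609, signal 22.1). Il2 had 2 regions, 1 of them at its promoter. Il4 and Il17a had no region in the thresholded list and 2 and 1 in the pseudoreplicated list. Stat4 (7 regions), Gata3 (6), Rora (8) and Tox (11), which are factors of other T cell states, also carried regions. Among cytotoxic genes, Fasl had 11 and Gzmb had 4, while Cd8a and Klrk1 had none in the thresholded list, and 1 and 0 in the pseudoreplicated list.

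Over all protein-coding genes, 24746 regions (94.8%) were assigned to 11644 genes, of which 178 had 10 or more. After Bach2 came Prkch (26 regions), Foxp1 (24), Akap13 (22), Itpr1 (20), Pde4d and Prkcq (19 each), Smad7 and Sgms1 (18 each), and Trio, Lclat1, Dock10, Nfatc1 and Fyn (17 each). This order is by count alone, and a large territory can gather more regions. Territories were 183 kb for Prkch, 705 kb for Foxp1 and 1565 kb for Pde4d, against a median of 45.0 kb over all genes. Prkcq, which encodes protein kinase C theta, Fyn, a kinase of T cell receptor signalling, Itpr1, a calcium channel of the endoplasmic reticulum, and Nfatc1, a calcium-dependent transcription factor, act downstream of the T cell receptor. In the pan-T cell list Ets1 had the most regions (15), and Runx1, Runx3 and Bcl11b had 11 each. Of genes of other lineages, Klrb1c, which encodes the NK cell receptor NK1.1, had 8 distal regions, and Cd34 had 4, while Cd14, Cd68 and Apoa1 had none in the thresholded list, and 1, 0 and 0 in the pseudoreplicated list. The territories of Cd14, Cd68 and Apoa1 were small, at 19.6, 2.76 and 7.92 kb.

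At Foxp3 itself (chromosome X, 7573644 to 7595245, plus strand), 1 thresholded region was assigned to the gene. It lay in an intron at 7583656 to 7584406, with a signal of 10.1 and a −log10 p of 103. A further region at 7574178 to 7574981 (signal 9.99) was within 1000 bp of the most upstream annotated Foxp3 TSS and overlapped the promoter of the divergent gene Ppp1r3f, as did a weaker region at 7572420 to 7572803 (signal 4.35) near another Ppp1r3f TSS. Foxp3 counts among genes with a promoter region by these regions, which were assigned to Ppp1r3f. At the downstream TSSs around 7579669, the pseudoreplicated list held a region (7579504 to 7579796) with a signal of 2.34 and an IDR of 0.388, which did not pass the threshold. A site with its summit 283 bp from the most downstream annotated Foxp3 TSS, at 7586495 to 7586787 (signal 3.14), and a site near the gene's 3' end at 7593898 to 7594277 (signal 3.38) likewise did not pass the threshold.

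**Figure D3:**
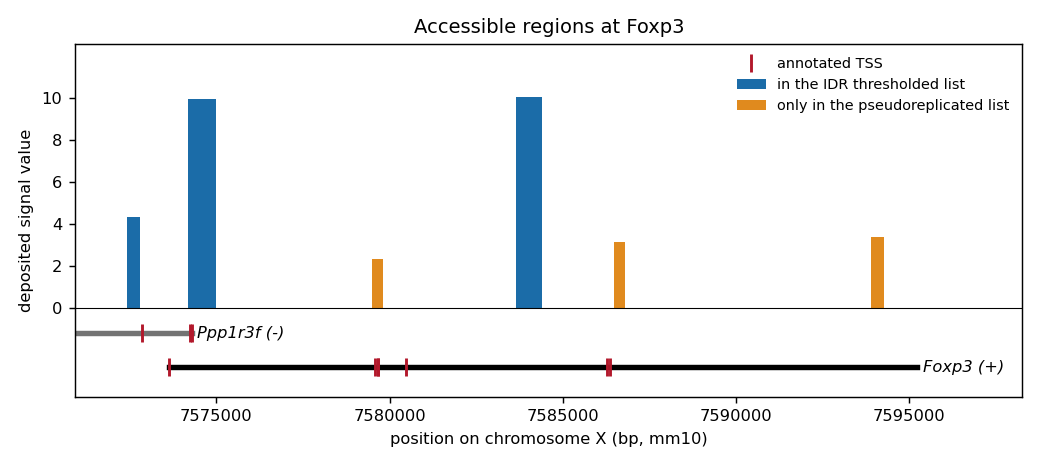
Deposited signal value (y axis) of the regions at Foxp3 along chromosome X (x axis, bp, mm10), with the gene bodies of Ppp1r3f and Foxp3 and their annotated TSSs below. Bars span each region: the intronic region reaches 10.1 and the region at the downstream TSSs reaches 2.34.

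Among promoter regions, that of Gm20594 had the highest signal (41.6), followed by Platr25 (35.1), 6720489N17Rik (34.9), Ccdc77 (34.2) and Exoc4 (33.9). The strongest distal regions lay on chromosome 2 near Abcb11 (69355469 to 69355735, signal 64.99), on chromosome X near Pak3 (143482935 to 143483180, signal 60.8) and on chromosome 10 near Gm5426 (96077484 to 96077951, signal 51.4). The Abcb11 and Gm5426 regions contain sequence that aligns to the mitochondrial genome, as does the next by signal, on chromosome 5 (60042667 to 60043155, signal 47.9). The TSS nearest to that chromosome 5 region, of G6pd2, lay 1765833 bp away, so the region was assigned to no gene. In that order, the longest alignment spanned 129, 373 and 383 bp. The highest identity of any alignment, not always the longest, was 100%, 97.6% and 97.9%.

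Short consensus motifs were compared between 48154 summit windows and flanks. Among factors of lymphocytes, ETS (ACMGGAAGT) was present at 3.75% of summits (95% interval 3.59 to 3.93) against 0.424% of flanks, an 8.86-fold excess. RUNX (TGTGGTTW) was present at 4.52% against 2.02% (2.24-fold), NF-kB (GGGRNTTTCC) at 1.49% against 0.326% (4.57-fold), AP-1 (TGASTCA) at 5.89% against 3.36% (1.75-fold) and IRF at 3.90% against 2.85% (1.37-fold). The CTCF core, which marks insulators, was found at 3.59% against 0.253% (14.2-fold). Motifs of broadly used promoter factors were also in excess, with NRF1 37.3-fold, CRE 14.02-fold, EGR 12.4-fold, YY1 9.69-fold and KLF/SP 8.90-fold above flanks. NRF1 and EGR were present at only 0.542% and 0.488% of summits. Over the alternatives the ratio ran from 29.4 to 60.5 for NRF1 and from 10.7 to 24.0 for CRE. It ran from 1.695 to 13.8 for EGR, from 7.35 to 15.1 for YY1 and from 5.39 to 9.60 for KLF/SP. ETS, RUNX, NF-kB, CTCF, NRF1, CRE, YY1 and KLF/SP were higher on 20 of 20 chromosomes tested, and AP-1 on 19. In total 17 of 32 motifs were called higher by the exact McNemar test, and 8 were called lower. The forkhead motif of Foxp3 and related factors was not called (2.75% against 2.86%, adjusted p = 0.338 by the exact McNemar test), nor was STAT (2.80% against 2.99%, adjusted p = 0.0749). At distal summits alone both were called higher than flanks, forkhead at 3.68% against 2.82% (1.31-fold, adjusted p = 5.28e-07 by the exact McNemar test, 17 of 20 chromosomes) and STAT at 3.44% against 2.95% (1.16-fold, adjusted p = 0.00522, 14 of 20). The BATF-IRF composite was found in 34 summit and 19 flank windows (adjusted p = 0.0650 by the exact McNemar test), and in the pseudoreplicated list it was called higher (2.52-fold, adjusted p 2.16e-05). In the stricter list forkhead (0.912-fold), STAT (0.899-fold) and T-box (0.786-fold) were called lower, and REST was called higher in the pseudoreplicated list (1.38-fold) and in windows of 50 bp.

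Summit windows had a GC content of 55.9% against 44.9% in flanks, and the ratios of many motifs depended on that background. NFAT (0.496-fold), GATA (0.711-fold) and TCF/LEF (0.843-fold) were lower at all summits. Against dinucleotide-shuffled summit windows NFAT was 1.02-fold and not called, while GATA (1.197-fold) and TCF/LEF (1.12-fold) were called higher, as were forkhead (1.83-fold) and STAT (2.15-fold). Among motifs called higher at all summits, the ratio against shuffled windows was larger for ETS (16.8-fold), IRF (4.43-fold) and RUNX (3.42-fold) and smaller for EGR (1.695-fold), KLF/SP (5.39-fold), CTCF (9.39-fold) and NF-kB (3.46-fold).

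Distal summits carried a different set of motifs from promoter summits. In 22793 distal windows against 25875 promoter windows, RUNX was present at 7.89% against 1.53% (5.17-fold), CTCF at 6.26% against 1.202% (5.21-fold), AP-1 at 9.41% against 2.76% (3.41-fold), NF-kB at 2.21% against 0.846% (2.61-fold), IRF at 5.70% against 2.30% (2.48-fold), TCF/LEF at 9.79% against 4.22% (2.32-fold) and ETS at 5.19% against 2.43% (2.14-fold). GATA (2.84-fold), ROR (2.63-fold) and NR4A (2.58-fold) were also higher at distal than at promoter summits, but against distal flanks their ratios were 1.05, 1.01 and 1.09 and none was called. The BATF-IRF composite was at 0.114% against 0.0348% (adjusted p = 0.00135 by Fisher's exact test). In the other direction, KLF/SP was at 2.11% against 11.1%, NRF1 at 0.132% against 0.9005%, YY1 at 0.294% against 1.72% and CRE at 0.755% against 1.91%. In all, 20 motifs were called higher at distal summits, 8 were called higher at promoter summits and 4 were not called (HNF1, HNF4, REST and GRHL), of which HNF1 was called higher at distal summits with promoter windows of 2500 bp. Distal windows had a GC content of 49.6% and promoter windows 61.5%.

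**Figure D4:**
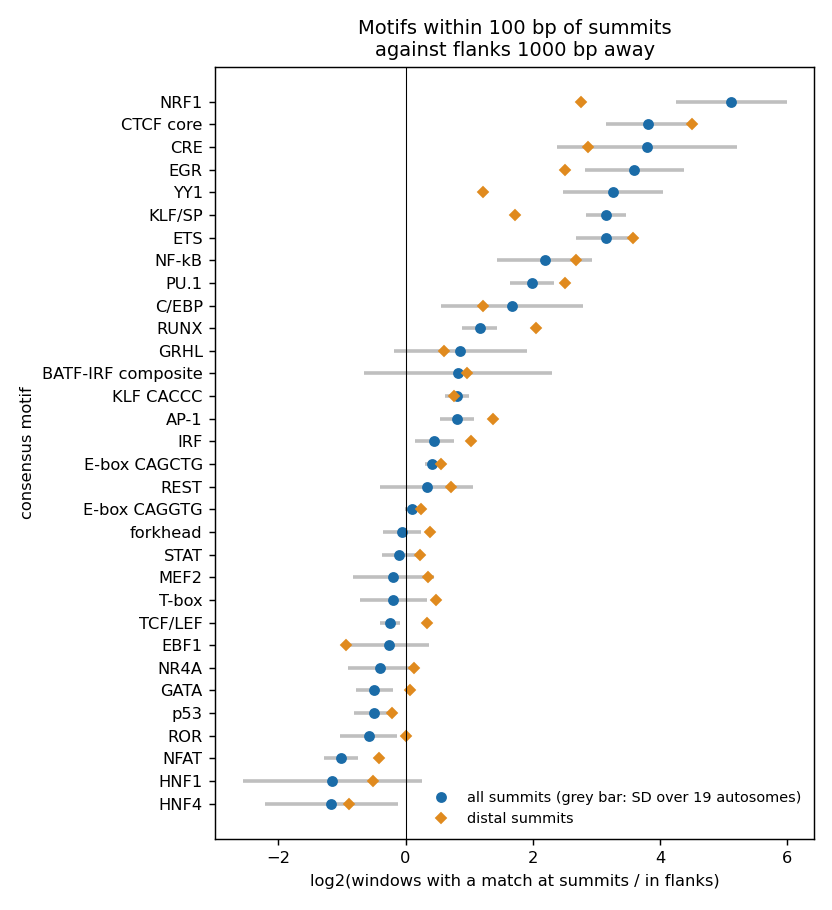
Log2 ratio of windows with a motif at summits to windows with it in flanks (x axis) for each consensus motif (y axis), at all summits with the SD over the 19 autosomes as bars, and at distal summits. ETS lies at 3.14 over all summits and 3.57 at distal summits, and TCF/LEF at −0.25 and 0.34.

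Some motifs became more frequent with the signal of the peak. The bins hold single peaks, and a region can hold several. The second weakest bin ended at a signal of 6.75, below the lower quartile of regions at their strongest peak (9.89). Weak bins may thus hold many secondary summits of stronger regions, at distal summits as well. The rises below therefore do not compare weak with strong regions. In 5 equal bins of signal, ETS rose in every step from 0.729% to 6.23%, as did KLF/SP (2.85% to 9.64%), CRE (0.164% to 3.08%) and YY1 (0.236% to 2.08%). Within distal summits alone, ETS rose from 1.16% to 7.96%, RUNX from 3.66% to 10.9%, AP-1 from 5.48% to 12.4% and TCF/LEF from 7.90% to 10.97% through all 5 bins. KLF/SP (1.49% to 2.48%), CRE (0.285% to 1.29%) and YY1 (0.154% to 0.439%) did not rise in every step at distal summits. CTCF was highest in the next to strongest distal bin (10.2%, against 0.856% in the weakest). NFAT was at 2.48% in the weakest and 1.602% in the strongest distal bin.

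Chromosome X, present in 1 copy in male cells, carried 612 regions, or 3.74 per Mb, which was 0.362 times the autosome median of 10.3. All 19 autosomes were denser, from 7.60 on chromosome 14 to 14.1 on chromosome 11. Per protein-coding gene, X had 0.646 regions against an autosome median of 1.22 and a lowest autosome of 0.841. Of X genes 34.4% (326 of 948, 95% interval 31.4 to 37.5) had a promoter region, against 50.2% of autosomal genes. The regions that were present on X had a median signal of 14.95, above the autosomes (13.2 to 13.98), but in the pseudoreplicated list it was 8.77, within the autosome range of 8.25 to 9.11. Chromosome Y carried 7 regions.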

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

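The counts of peaks that the thresholded list lacks were chosen after the lists had been compared. In the ranked list, 58 peaks past an IDR of 0.05 lay on 10 sequences outside chromosomes 1 to 19, X and Y, and 121 lay on those chromosomes but were absent from the thresholded list. Both counts are above the limit of 3 set for flagging, which is not a statistical test, and there were no control samples to compare them with. The unplaced sequence JH584304 held 33 of these peaks in 17 regions. On chromosome 1, 14 summits fell in a single stretch of 4591 bp near Col19a1 (24611567 to 24616157), with a −log10 p of 2262. The highest −log10 p among these peaks, 3062, lay on chromosome 6 near Chl1 (103648979 to 103649358). The 179 peaks had a median signal value of 4.89 and a median −log10 p of 66.6, against 8.68 and 42.4 for peaks of the thresholded list. How the thresholded list was filtered is not given in the sources used here, and no explanation was tested.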

How the results depend on the processing

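No test in this part was chosen after the results were seen. No paired analysis was possible because the design holds 1 group, and no replicate could be left out because the lists pool both libraries. What sequencing depth limits is unknown, since the lists give no read counts. Requiring an overlap of 50% could not test the sharing values, since 48616 of the 48668 thresholded peaks have the same intervals in the pseudoreplicated list. Over all alternatives run, 7 of 8 higher and 2 of 4 lower promoter calls held, as did 12 of 15 higher and 1 of 1 lower calls for regions per gene, 12 of 15 for distal regions, 14 of 17 higher and 2 of 8 lower motif calls, and all 20 higher and 8 lower calls between distal and promoter summits.

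Unmerged, with each interval counted once per summit, the thresholded list held 48668 peaks. The stricter list shared 39.6% of pseudoreplicated regions, and the Spearman correlation of the inputs was 0.730 over peaks past the threshold, a choice of peaks made by the agreement of the same inputs, so that it tests nothing. The promoter share of regions was 30.1% in the pseudoreplicated list, 48.8% in the stricter list, and 38.4% and 47.9% with windows of 500 and 2500 bp. In the stricter list 8 lists were lower at promoters and 2 by regions per gene, and assignment within 20 kb also gave 2. Against shuffled windows 3 motifs were called lower (ROR, HNF4 and EBF1), of which EBF1 was not called in the original setting. In the pseudoreplicated list X density was 0.403 of the autosome median.

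The remaining values changed sign, and the cause was not tested. As percentage points above other genes, Th1 promoters were at −5.19 with 1 TSS per gene, and erythroid promoters at 4.34 in the pseudoreplicated list. CD8 promoters were at 13.6 in the pseudoreplicated list, 2.94 with 2500 bp and 0.968 with 1 TSS per gene. For regions per gene (log2), the pseudoreplicated list gave 0.50 for Th17, 0.11 for myeloid, 0.35 for NK cell and 0.16 for erythroid genes. The stricter list gave −0.19 for B cell and −0.0874 for epithelium genes. Assignment within 50 kb gave 0.0223 for Th17, −0.0947 for B cell and −0.0478 for epithelium, and within 20 kb −0.21 for B cell, 0.0276 for NK cell and −0.20 for epithelium. Without matching, Th17 was at 0.0923 and B cell at −0.0253, and with unmerged peaks B cell was at −0.18 and epithelium at −0.0110. For distal regions, stem and progenitor genes were at 0.0721 in the stricter list and 0.0677 without matching, and neuron genes at 0.0400 in the pseudoreplicated list. Against shuffled windows the log2 motif ratios were 0.16 for TCF/LEF, −0.0120 for CAGGTG, 0.87 for forkhead, 0.0333 for NFAT, 1.10 for STAT, 0.26 for GATA, −0.15 for C/EBP, 0.45 for HNF1 and 1.44 for MEF2. In the pseudoreplicated list forkhead was at 0.0368, STAT at 0.0670 and MEF2 at 0.0264, and T-box was at 0.00677 in windows of 50 bp. Between distal and promoter summits with 2500 bp, HNF4 was at −0.23 and REST at 0.0463. None of the reversed values was called in the original setting, except those of TCF/LEF, CAGGTG, NFAT, GATA, C/EBP and HNF1.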

Other observations

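The gene families and receptor loci here, and the test of X regions per gene, were chosen after the data were seen, and the families were counted without a test. Promoter regions were present for 79 of 83 ribosomal protein genes, 76 of 78 mitochondrial ribosomal protein genes, 62 of 67 histone genes, 37 of 40 proteasome subunits and 282 of 394 Zfp zinc finger genes. They were present for 7 of 1134 olfactory receptors, 1 of 328 vomeronasal receptors, 1 of 49 keratins and 5 of 39 Hox genes. Among immune families, all 7 Stat factors, 8 of 9 Irf factors, 7 of 8 Gimap GTPases, 13 of 20 Tnfrsf receptors and 20 of 41 interleukin receptors had one, against 4 of 31 interleukins and 2 of 35 CC and CXC chemokines. Chemokine receptors had 3.06 regions per gene, led by Cxcr5 with 10, and Irf factors 3.44, led by Irf4 with 9. Killer cell lectin-like receptors had no promoter region among 26 genes but 19 assigned regions, of which 8 belonged to Klrb1c.

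Antigen receptor loci differed in density. For scale, whole autosomes had a median of 10.3 regions per Mb and ran from 7.60 to 14.1. The gamma, alpha and delta, and heavy chain loci lay within that range. The T cell receptor beta locus held 11 regions (16.5 per Mb), the gamma locus 2 (11.4 per Mb) and the alpha and delta locus 19 (10.6 per Mb). Within 10 kb of the constant genes lay 5 regions at Trac, 4 at Trbc2 and 2 at Trbc1, windows that overlap for the last pair, while Trdc had none. Ighm, Ighg3 and Igkc had 1 each. The immunoglobulin heavy chain locus held 29 regions (10.6 per Mb), the kappa locus 4 (1.26 per Mb) and the lambda locus 0. In the pseudoreplicated list the heavy chain locus held 72 regions over 2.75 Mb, and the alpha and delta locus 74 over 1.80 Mb. The beta locus held 36 there, the gamma and kappa loci 7 each and the lambda locus 0. The widest region of the list spanned 2782 bp at the Tsc22d2 promoter, and that at Stat6 spanned 2328 bp.

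The 20 regions with the highest −log10 p included 10 that align to the mitochondrial genome at 90% identity or more over 100 bp or more, among them all of the top 7, against 0 of 200 random regions. Similarity to mitochondrial DNA may therefore account for those 10. Whether their reads came from the nuclear copies or from the mitochondrial genome itself was not tested. Sequence repeated elsewhere in the nuclear genome was found in 6 of the 20, against 1 of 200 random regions, and stays open. Neither applied to 9 of the 20, most of them promoters such as those of Sel1l, Uggt2 and Tmx2. No biological explanation was tested, since the design has 1 group.

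The low density of regions on X was not due to fewer genes alone, since X had 0.646 regions per protein-coding gene, below the lowest autosome at 0.841. Fewer reads from the single X copy remain open. At distal summits with a CTCF core in the pseudoreplicated list, the median −log10 p on X was 0.787 times that on autosomes (95% interval 0.595 to 0.916), between the values that would argue for and against this explanation. Only called peaks entered this ratio. Sites on X too weak to be called are missing from it, so it cannot decide the question. No biological explanation was tested.

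The 8 motifs called less frequent at summits than in flanks had a median log2 ratio of −0.54, and the same motifs written backwards had −0.69. Base composition of the summit windows may therefore account for part of the pattern. Against dinucleotide-shuffled summit windows, ROR (0.797-fold) and HNF4 (0.496-fold) were still called lower. In that setting TCF/LEF and GATA were called higher, and NFAT, NR4A, HNF1 and p53 were not called. The pattern may also rest on GC-rich promoter summits, since at distal summits 2 of the 8 motifs, NFAT and HNF4, were still called lower, while TCF/LEF was 1.27-fold higher. No biological explanation was tested.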
